A study of Mus musculus with 8 samples.

How the data were processed

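Gene expression was measured in cells sorted from gastrulating mouse embryos that carried a Mesp1-driven reverse tetracycline transactivator and a tetracycline-responsive histone H2B-GFP. The nuclear GFP reported activity of this Mesp1-driven system, which need not match all Mesp1 expression. Per the labels, embryos were dissociated with trypsin, living cells were selected by exclusion of propidium iodide, and 50 GFP+ or 50 GFP- cells were collected at embryonic day (E) 6.5 or 7.5. RNA was purified on magnetic beads and reverse transcribed, and the cDNA was amplified by whole-transcriptome amplification, stopped after 25 PCR cycles. The labelled product was hybridized to an Affymetrix mouse perfect-match array. The 8 arrays formed 4 groups (fraction by stage) of 2 arrays, which the labels name biological replicates 1 and 2. The labels do not say whether arrays of 1 replicate number came from the same embryos or litter.

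The deposited values were log2 expression values per probe set, made by the authors with RMA (background correction, quantile normalization and summary of probes) per the submitters' processing notes. The RMA version and a genome build were not given in the sources used here. No coordinates were used for that reason. The number of arrays limits the precision, and amplification from 50 cells adds sampling noise that these values cannot separate from biological spread. Array medians were 4.20 to 4.23 on the log2 scale for replicate 1 and 4.54 to 4.59 for replicate 2. Sorted values differed by a mean of 0.0174 within the replicate 1 arrays and 0.0155 within the replicate 2 arrays, but by 0.227 between these sets. The distributions therefore looked as if each replicate number had been normalized separately, which no label states.

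The table held 45141 probe sets, of which 104 were controls. In the platform annotation used here, 28898 of the others had 1 gene symbol, 551 had several and 15588 were unnamed. Names were taken only from probe sets with 1 symbol, covering 17097 symbols. Of these probe sets 28689 matched a current gene of the GRCm38.p6 annotation by Entrez identifier, and 0 symbols changed. A probe set was kept when at least 2 of the 8 arrays lay above the median of all deposited values (4.38 on the log2 scale), which left 18584 named probe sets. The files used here held no measure of background per probe set, so the size of a change against a group whose mean lay below that value is uncertain. Such genes are pointed out beside their values. Each gene was represented by its probe set with the highest mean, giving 11706 genes. Other probe sets of a gene can disagree, and the mean of all of them was tried as an alternative.

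Groups, tests, gene lists and most alternatives were fixed before the data were examined. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 8 arrays with a mean per group and no pairing, leaving 4 residual degrees of freedom and a prior of 3.21. All 8 arrays shared 1 estimate of the spread. There were 5 contrasts: GFP+ against GFP- at E6.5 and at E7.5, E7.5 against E6.5 in GFP+ and in GFP- cells, and the interaction of fraction and stage (the E7.5 difference between fractions minus that at E6.5). Genes passed at a Benjamini-Hochberg adjusted p under 0.05. All changes are on the log2 scale, with the standard error (SE) of the fit, and tests were two-sided unless stated.

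Replicate numbers are shared by the 4 groups, so their pairing was checked. Across genes, the deviations of same-numbered arrays from their group means correlated for all 6 pairs of groups (r from 0.401 to 0.532). The first principal component, with 36.6% of the variance, separated the replicate numbers. Arrays of the same group correlated at r = 0.915 to 0.950 and arrays of the same number but another group at 0.908 to 0.969. Arrays of a replicate number therefore shared an offset. The correlations between fractions of 1 stage (0.476 at E6.5, 0.487 at E7.5) lay among those between stages. They do not show that the fractions came from the same embryos. The main fit, fixed in advance, has no block, so its spread includes this offset and its SE and adjusted p carry it. Fits with the replicate number as a block were run as alternatives fixed in advance. Genes are not independent replicates in these correlations.

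Gene lists were tested with camera at its preset correlation of 0.01, adjusted over 140 tests (28 lists by 5 contrasts). The lists covered the primitive streak and nascent mesoderm, mesenchymal genes of the epithelial-mesenchymal transition, epithelial genes, the first and the second heart field, cardiomyocyte contraction, endothelial and haematopoietic progenitors, erythroid cells, epiblast and pluripotency, anterior epiblast and neural ectoderm, and surface ectoderm. Further lists covered definitive endoderm and node, visceral endoderm, extraembryonic ectoderm, extraembryonic mesoderm, paraxial mesoderm, Hox genes, primordial germ cells, the Wnt, BMP, FGF and Notch pathways, guidance receptors and ligands, and extracellular matrix. The last 4 covered glycolysis and hypoxia, the cell cycle, dissociation stress, and X inactivation with sex-linked genes. Of 492 listed genes, 376 were tested, 74 lay below the filter and 42 had no probe set named here, and 41 of the tested genes stood in more than 1 list. Camera with an estimated correlation between genes and fry were alternatives. With an estimated correlation camera takes its p from the 4 residual degrees of freedom of the fit. Few lists could then pass over 140 tests, so a failure to pass there is weak evidence that a list did not shift. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. The sign of a list's median or mean differed from that of its test in 16 of the 140 tests, of which 0 passed the threshold.

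The text names the 8 genes with the largest rise and the 8 with the largest fall per comparison among those that passed and whose groups did not overlap (5 each way for the interaction), and all where fewer passed. It draws also on 22 developmental genes fixed in advance, of which 20 had a tested value and the others are not analysed here. Of each list it may name up to 4 members with the largest change among those past the threshold, or among all members where none passed. Unnamed clones were skipped. Cited2, Lhfp, Pecam1 and, between the stages, Hoxd9, Hoxa2 and (in GFP- cells) Hoxa3 fell outside this rule and were chosen after their values were seen. Alternatives covered no filter and a stricter one (at least 2 arrays above the 75th percentile), moderation with trend and robust settings, only the 4 arrays of a comparison, the replicate number as a block, a random block within stage, the mean of probe sets, quantile normalization again, centring on array medians, array weights, a minimum change of 2-fold and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.

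The procedure was tested on simulated data for the E6.5 comparison, with 11706 genes, in 5 simulations. Of these genes 200 were changed, and a separate list of 20 was shifted upward and not counted among the false calls. The fit without a block recovered 0% of genes changed 2-fold and 49.6% of those changed 8-fold, with 1 false call among 249. The blocked fit recovered 4.6% and 76%, with 23 false calls among 428. The shifted list of 20 genes passed at an unadjusted camera p under 0.05 in 5 of 5 simulations and an unshifted list in 0 of 5. The simulated noise was independent between genes and the lists were drawn at random. The simulation therefore could not show how the list test behaves when members of a list vary together.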

Results

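The data comprised 8 arrays of amplified RNA from 50 sorted cells each, from mouse embryos at the onset of gastrulation (E6.5) and a day later (E7.5). GFP+ cells were positive for a Mesp1 reporter when sorted and GFP- cells were not. Mesp1 encodes a transcription factor of the earliest mesoderm, including the progenitors of the heart, and the series title places the study in the early restriction of heart lineages. Each fraction and stage had 2 arrays, numbered 1 and 2, and every group mean below is over these 2 arrays. The replicate numbers differed more than many groups did (36.6% of the variance lay on a component that separated them), so changes within each number are given where a result rests on them. The P values of single genes come from limma with Benjamini-Hochberg adjustment over 11706 genes, and those of gene lists from camera over 140 tests.

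The comparison of fractions at E6.5 asked which genes marked the first Mesp1-expressing cells. GFP+ cells had higher levels of primitive streak, mesenchymal, paraxial mesoderm and Wnt target genes, and lower levels of epithelial, epiblast and visceral endoderm genes. None of these 7 lists passed with an estimated correlation (adjusted p = 0.0956 to 0.271 with an estimated correlation). Mesp1 itself rose from 5.95 ± 0.44 in GFP- to 9.89 ± 0.19 in GFP+ cells (mean ± SD, log2). The change was 3.94 (SE 0.33, 15.3-fold, limma adjusted p = 0.0209), with 4.11 and 3.76 within replicates 1 and 2. Aplnr, a receptor for the migration signals apelin and Apela, rose by 5.11 (SE 0.30, limma adjusted p = 0.00553). Its other probe set, with a mean of 7.80 against 8.14 for the one used, gave a smaller rise of 2.08. Snai1, a repressor of E-cadherin that drives cells out of an epithelium, rose by 3.13 (SE 0.34, limma adjusted p = 0.0495). Fn1, which encodes the matrix protein fibronectin, rose by 3.18 (SE 0.28, limma adjusted p = 0.0214). The transcription factor genes Meis2 (3.61), Sp5 (3.40, a Wnt target) and Hoxb1 (3.33) also rose, as did Dlc1 (3.57), and Dtx1, a Notch pathway regulator, fell by 3.24. These 8 genes up and 1 down were all that passed. In GFP- cells Aplnr (3.49), Hoxb1 (3.52) and Meis2 (4.10) lay below the filter value of 4.38, as did Dtx1 (4.29) in GFP+ cells, so the sizes of these 4 changes are uncertain.

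Of the 19 measured streak genes, 14 were higher and 0 lower in GFP+ cells when adjusted over the list alone, and 2 over all genes. Their median change was 2.44 (2.20 and 2.03 within replicates 1 and 2, camera adjusted p = 3.91e-23, adjusted p = 0.0956 with an estimated correlation). Mixl1, a homeobox gene of the streak, was 4.54 higher (SE 1.09, 6.41 and 2.67 within the replicates, 2.84 without GFP- E6.5 replicate 1), and Eomes, which acts upstream of Mesp1, was 1.40 higher (SE 0.53). Paraxial mesoderm genes rose as a list by a median of 1.18, with 6 of 17 higher adjusted over the list alone (camera adjusted p = 1.25e-07, adjusted p = 0.271 with an estimated correlation). Among these were the Notch ligand gene Dll3 (3.81, SE 0.59), Mesp2 (2.78, SE 0.54) and Tbx6 (2.54, SE 0.49). Mesp2 and Tbx6 lay below 4.38 in GFP- cells, so the sizes of their differences are uncertain. Mesenchymal genes had a median of 0.98, with 4 of 17 higher adjusted over the list alone (camera adjusted p = 3.04e-08, adjusted p = 0.271 with an estimated correlation). Wnt targets had a median of 0.76, with 4 higher and 1 lower of 15 adjusted over the list alone (camera adjusted p = 1e-07, adjusted p = 0.0956 with an estimated correlation).

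Epithelial genes fell as a list at E6.5 by a median of -1.64 (-1.53 and -1.52 within the replicates), and 10 of 18 were lower adjusted over the list alone (camera adjusted p = 2.96e-18, adjusted p = 0.0956 with an estimated correlation). Cdh1, the gene of E-cadherin, was at -2.16 (SE 0.31), the keratin gene Krt18 at -2.74 (SE 0.42) and the tight junction gene Cldn4 at -2.44 (SE 0.57, -1.51 without GFP- E6.5 replicate 1). Epiblast genes had a median of -0.92, with 4 of 17 lower adjusted over the list alone (camera adjusted p = 1.49e-07, adjusted p = 0.0956 with an estimated correlation). Their largest differences were in Utf1 (-3.70, SE 0.78), Slc7a3 (-3.54, SE 0.68) and Grb7 (-3.07, SE 0.47), whereas Pou5f1, which encodes Oct4, was at 0.06 (SE 0.32). Visceral endoderm genes moved with both groups. Their median was -2.52 (-1.49 and -3.42 within replicates 1 and 2), with 10 of 15 lower adjusted over the list alone (camera adjusted p = 9.82e-15, adjusted p = 0.271 with an estimated correlation). The apolipoprotein gene Apoa1 was at -3.36 (SE 0.53), Dab2, which encodes an endocytic adaptor, at -3.34 (SE 0.80, -2.05 without GFP- E6.5 replicate 2), and Spink1 at -5.91 (SE 1.95). Cldn4 and Spink1 lay below 4.38 in GFP+ cells, so these sizes are uncertain. Afp, the alpha-fetoprotein gene, was at -1.14 (SE 0.56, -0.53 and -1.75 within the replicates, -0.40 without GFP- E6.5 replicate 2) on the probe set used, and at 0.04, -0.64, -3.79 and -5.17 on others.

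Among cardiac regulators at E6.5, the list of the first heart field had a median of 0.16 and 2 of 13 members higher adjusted over the list alone, Gata6 (3.63, SE 0.89, 5.23 and 2.03 within the replicates) and Bmp7 (2.83, SE 0.45). Bmp7 lay below 4.38 in GFP- cells, so its size is uncertain. Gata4 was at 2.76 (SE 0.88, 3.90 and 1.62 within the replicates) and Hand1 at 1.69 (SE 0.88, 0.86 and 2.53). Without GFP- E6.5 replicate 1, Gata6 was at 2.05 and Gata4 at 1.25, and without GFP+ E6.5 replicate 2 Hand1 was at 0.67. This list passed (camera adjusted p = 0.00428, adjusted p = 0.402 with an estimated correlation), but not without GFP+ E6.5 replicate 2 (0.0700). The list of the second heart field passed with a median of 0.15 and 1 of 12 higher adjusted over the list alone, Hoxb1 (camera adjusted p = 0.0241, adjusted p = 0.356 with an estimated correlation). It did not pass without GFP+ E6.5 replicate 2 (0.0758) or GFP- E6.5 replicate 2 (0.0901). Of later regulators of heart cells, Isl1 and Tbx5 were at -0.04 (SE 0.42) and 0.03 (SE 0.32), and Nkx2-5 lay below 4.38 in both fractions. Contractile genes did not pass (camera adjusted p = 0.78), nor did endothelial and haematopoietic genes (0.874), in which Kdr, the gene of a VEGF receptor, was at 2.90 (SE 0.80).

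At E6.5, 4 other lists also passed. Definitive endoderm genes had a median of -0.78, with 1 of 12, Trh (-3.33, SE 0.61), lower adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.309 with an estimated correlation). Extraembryonic ectoderm genes had a median of -0.35, with 1 of 15, Rhox5 (-4.34, SE 0.86), lower adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.425 with an estimated correlation). Primordial germ cell genes had a median of 0.48, with 1 of 5, Ifitm1 (2.92, SE 0.65, 1.86 without GFP- E6.5 replicate 1), higher adjusted over the list alone (camera adjusted p = 0.00947, adjusted p = 0.283 with an estimated correlation). Matrix genes had a median of 0.28, with 2 of 18 higher adjusted over the list alone (camera adjusted p = 0.00172, adjusted p = 0.307 with an estimated correlation). These calls ended without GFP- E6.5 replicate 2 (definitive endoderm 0.149, extraembryonic ectoderm 0.190), GFP+ E6.5 replicate 2 (extraembryonic ectoderm 0.0656) or GFP- E6.5 replicate 1 (germ cells 0.0791, matrix 0.101), and that of germ cells also with no filter (0.409).

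Of 11706 genes, 9 passed at E6.5, against 30 (18 up, 12 down) with the replicate number as a block, which held all 9, and 173 (73 up, 100 down) with a random block within stage. Without any 1 of the 4 E6.5 arrays 0 genes passed, and without any 1 of the E7.5 arrays 1 passed. With only the 4 arrays of the comparison none of the 9 passed (limma adjusted p = 0.101 for Aplnr and 0.158 for the others), with no filter Snai1 (0.0534), Sp5 and Dtx1 (both 0.0556) did not, and with the mean of all probe sets Dlc1 (0.137) and Meis2 (0.295) did not. At an unadjusted p under 0.05 limma gave 671 genes, and 1261 with the replicate block, where chance gives 585.3.

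**Figure D1:**
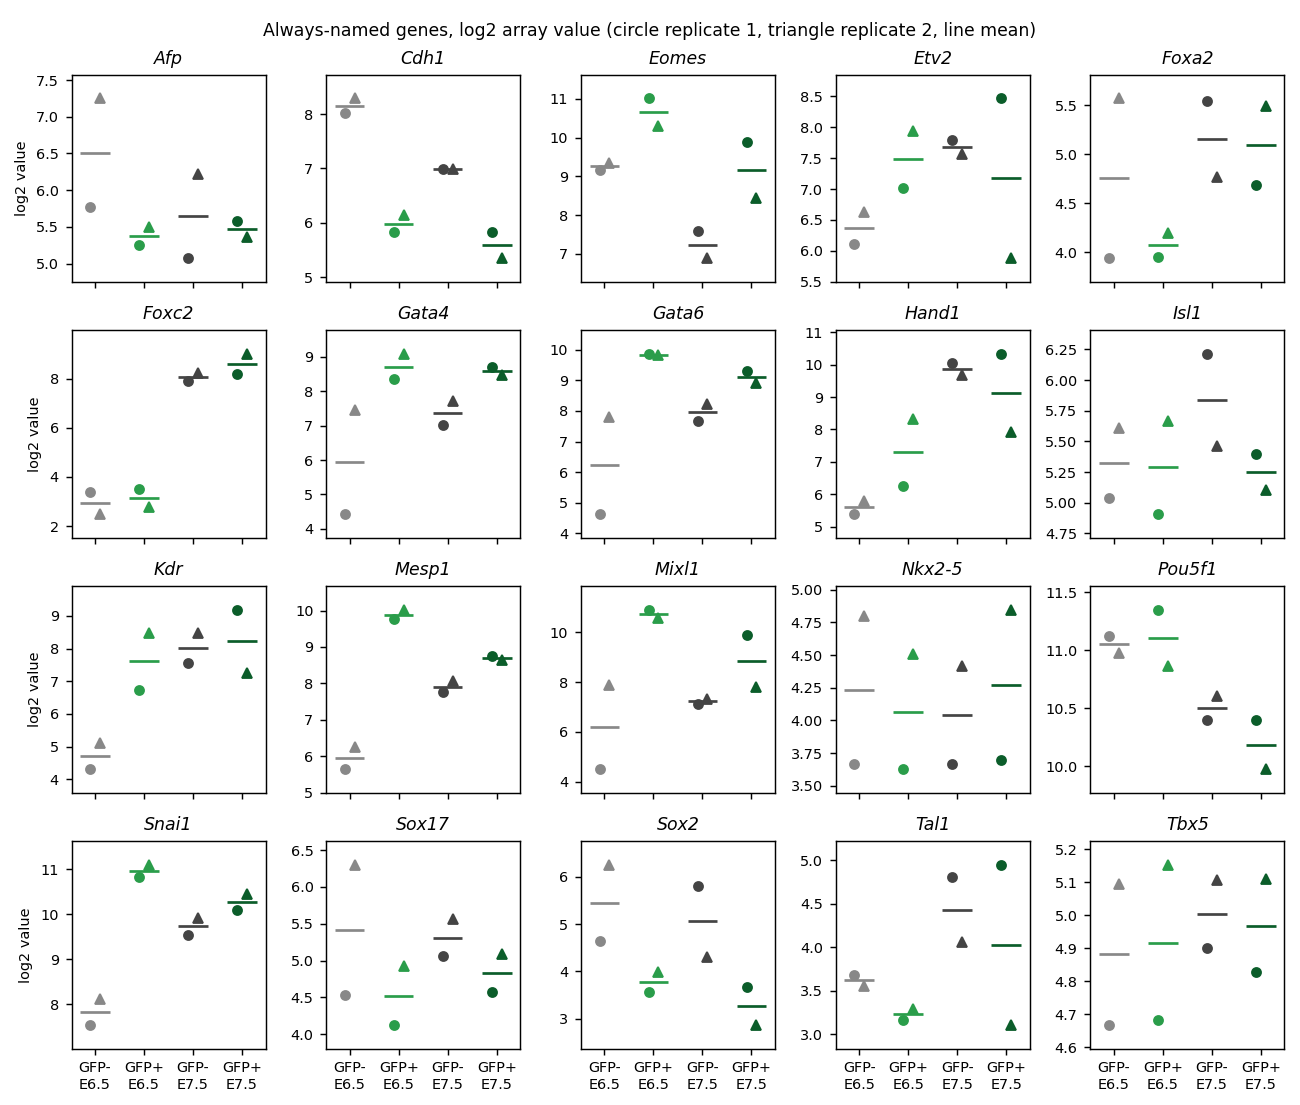
Log2 expression of the 20 developmental genes fixed in advance, on the vertical axis, in the 4 groups of cells; circles are replicate 1, triangles replicate 2 and lines the mean of the 2 arrays. Mesp1 lies at 9.89 in GFP+ and 5.95 in GFP- cells at E6.5, and at 8.70 and 7.91 at E7.5.

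At E7.5 the same comparison asked what separated the fractions a day later. Differences between fractions ran the same way for streak, paraxial, epithelial and epiblast genes as lists, but no single gene passed. None of these 4 lists passed with an estimated correlation (adjusted p = 0.0956 to 0.283 with an estimated correlation). Mesp1 was at 7.91 ± 0.21 in GFP- and 8.70 ± 0.07 in GFP+ cells, a difference of 0.79 (SE 0.33, 0.98 and 0.59 within the replicates). Streak genes had a median of 0.79 (0.55 and 0.49 within the replicates), with 0 of 19 past the threshold adjusted over the list alone (camera adjusted p = 1.44e-05, adjusted p = 0.283 with an estimated correlation). The largest differences were in Eomes (1.93, SE 0.53, 1.21 without GFP+ E7.5 replicate 1), Mixl1 (1.62, SE 1.09, 2.76 and 0.49 within the replicates, 0.59 without GFP+ E7.5 replicate 1) and Mesp2 (1.44, SE 0.54, 0.51 and 2.37, 0.57 without GFP+ E7.5 replicate 2). Paraxial mesoderm genes had a median of 0.95, with 0 of 17 past it adjusted over the list alone (camera adjusted p = 1.13e-05, adjusted p = 0.283 with an estimated correlation). Their largest differences were in Meox1 (2.13, SE 0.91, 1.31 and 2.95 within the replicates, 0.63 without GFP+ E7.5 replicate 2), a somite gene, the Notch modifier gene Lfng (1.65, SE 0.50) and the Notch ligand gene Dll1 (1.45, SE 0.34). In GFP- cells Mesp2 and Meox1 lay below 4.38, so the sizes of these 2 are uncertain.

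Epithelial genes were lower in GFP+ cells at E7.5 by a median of -0.54, with Cdh1 (-1.39, SE 0.31) and Cldn4 (-2.36, SE 0.57) the 2 of 18 lower adjusted over the list alone (camera adjusted p = 2.31e-08, adjusted p = 0.0956 with an estimated correlation). Epiblast genes had a median of -0.50 (-0.23 and -0.87 within the replicates), with 4 lower and 1 higher of 17 adjusted over the list alone (camera adjusted p = 8.06e-07, adjusted p = 0.0956 with an estimated correlation). Among these, Utf1 was at -2.85 (SE 0.78), Slc7a3 at -2.50 (SE 0.68) and the kinase gene Pim2 at -1.99 (SE 0.39). Extraembryonic ectoderm genes had a median of -0.84, with Rhox5 at -2.60 (SE 0.86, -4.15 and -1.05 within the replicates, -1.27 without GFP- E7.5 replicate 1), and 0 of 15 past it adjusted over the list alone (camera adjusted p = 1.5e-06, adjusted p = 0.271 with an estimated correlation). That call ended without GFP- E7.5 replicate 1 (0.402). Visceral endoderm genes did not pass (camera adjusted p = 0.0684). The size for Cldn4 is uncertain, since it lay below 4.38 in GFP+ cells.

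Contractile genes passed at E7.5 with a median of 0.05 and 1 of 13 higher adjusted over the list alone, Tnnc1, which encodes cardiac troponin C (3.35, SE 0.54, 2.28 and 4.41 within the replicates; camera adjusted p = 0.0417, adjusted p = 0.598 with an estimated correlation). Tnnc1 lay below 4.38 in GFP- cells, so this size is uncertain. Actc1, cardiac actin, was at 1.43 (SE 0.72, 1.99 and 0.87 within the replicates, 0.42 without GFP- E7.5 replicate 1). Notch pathway genes had a median of 0.44 and glycolysis genes of -0.12, with 0 of 15 and 0 of 17 past it adjusted over the list alone (camera adjusted p = 0.00265 and 0.0291, adjusted p = 0.359 and 0.312 with an estimated correlation). With the replicate block, contractile (0.0908) and glycolysis genes (0.0525) no longer passed, and mesenchymal genes passed (0.00968 against 0.0548 without it; adjusted p = 0.216 with an estimated correlation and the block). Without GFP- E7.5 replicate 1 the contractile (0.816), glycolysis (0.868) and Notch (0.160) calls ended, and so they did without GFP+ E7.5 replicate 2 (0.564, 0.646 and 0.0783). The contractile call ended also without GFP- E6.5 replicate 1 (0.0557) or replicate 2 (0.0575). The lists of the first (0.717) and the second heart field (0.671) did not pass.

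In GFP- cells at E7.5, Hbb-bh1, an embryonic globin gene, was higher: the GFP+ minus GFP- difference was -2.43 (SE 0.31), past the threshold adjusted over the erythroid list alone, although the list did not pass (camera adjusted p = 0.106). Its level in GFP+ cells (3.29) lay below 4.38, so the size is uncertain. Id2, a target of BMP signals, was at -2.25 (SE 0.41) and passed within the BMP list alone, and that list did not pass (0.321). At E7.5, limma called 0 of 11706 genes, with or without the replicate block, and 1, Hbb-bh1, with a random block within stage (limma adjusted p = 0.0487). At an unadjusted p under 0.05 there were 282 genes, and 755 with the replicate block, where chance gives 585.3. The fit without the block keeps differences between the replicate numbers in its spread.

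The comparison of E7.5 with E6.5 in GFP+ cells asked what changed within the Mesp1 reporter population. Genes of paraxial mesoderm, extraembryonic mesoderm and Hox clusters rose as lists, and epiblast and streak genes fell. None of these 5 lists passed with an estimated correlation (adjusted p = 0.0956 to 0.390 with an estimated correlation). Aldh1a2, which encodes an enzyme that makes retinoic acid, rose from 3.27 to 9.55, by 6.28 (SE 0.55), and Foxc2, a forkhead gene of paraxial and vessel-forming mesoderm, by 5.45 (SE 0.46). At E6.5 Aldh1a2 and Foxc2 (3.14) lay below the filter value of 4.38, so the sizes of these changes are uncertain. Msgn1, a regulator of presomitic mesoderm, rose by 3.36 (SE 0.31, 10.3-fold, limma adjusted p = 0.0409 for Aldh1a2, Foxc2 and Msgn1 each). Paraxial mesoderm genes had a median of 1.72, and 11 of 17 were higher adjusted over the list alone (camera adjusted p = 3.22e-21, adjusted p = 0.0956 with an estimated correlation).

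Contractile genes in GFP+ cells had a median of 0.18 between the stages, and 5 of 13 were higher adjusted over the list alone (camera adjusted p = 1.58e-05, adjusted p = 0.359 with an estimated correlation). Among them were Tnni1 (3.74, SE 0.79), Tnnc1 (3.54, SE 0.54), Actc1 (3.10, SE 0.72) and Myl7 (2.46, SE 0.80, 1.28 without GFP+ E6.5 replicate 1). The sizes for Tnnc1 and Actc1 are uncertain, as both lay below 4.38 at E6.5. The list of the second heart field had a median of 0.16, with 4 higher and 1 lower of 12 adjusted over the list alone (camera adjusted p = 7.86e-05, adjusted p = 0.241 with an estimated correlation). The list of the first heart field had a median of 0.21 (0.35 and -0.15 within the replicates) with 0 of 13 past it adjusted over the list alone (camera adjusted p = 0.0174, adjusted p = 0.449 with an estimated correlation), and did not pass without GFP+ E6.5 replicate 1 (0.120) or GFP+ E7.5 replicate 1 (0.145). Isl1 was at -0.04 (SE 0.42), and Nkx2-5 lay below 4.38 at both stages. Extraembryonic mesoderm genes had a median of 0.97 (1.86 and 0.32 within replicates 1 and 2), with 3 of 13 higher adjusted over the list alone (camera adjusted p = 1.06e-07, adjusted p = 0.195 with an estimated correlation). These were Bmp4 (3.75, SE 0.59), Igf2 (2.88, SE 0.50) and Phlda2 (2.29, SE 0.48), with Bmp4 below 4.38 at E6.5 and its size uncertain.

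Hox genes in GFP+ cells had a median of 0.61, with 4 of 13 higher adjusted over the list alone (camera adjusted p = 1.01e-06, adjusted p = 0.271 with an estimated correlation). They were Hoxb2 (3.26, SE 0.50), Hoxb1 (3.12, SE 0.32), Hoxa3 (2.03, SE 0.51, 1.21 without GFP+ E7.5 replicate 2) and Hoxb3 (1.77, SE 0.32). Mesenchymal genes had a median of 0.63 (2 of 17 higher adjusted over the list alone, camera adjusted p = 8.06e-07, adjusted p = 0.279 with an estimated correlation). Definitive endoderm genes had a median of 0.77, with 2 of 12 higher adjusted over the list alone (camera adjusted p = 5.28e-05, adjusted p = 0.279 with an estimated correlation). Both, Cer1 (5.49, SE 1.20) and Nog (2.20, SE 0.52), encode secreted antagonists of growth factors. Matrix genes had a median of 0.44, with Fbn2 (2.96, SE 0.42) and Lama1 (2.92, SE 0.55) higher of 18 adjusted over the list alone (camera adjusted p = 4.37e-05, adjusted p = 0.271 with an estimated correlation). Guidance genes had a median of 0.58, with 5 higher and 1 lower of 31 adjusted over the list alone (camera adjusted p = 0.000114, adjusted p = 0.307 with an estimated correlation). Flrt2 (2.26, SE 0.47) and Aplnr (2.14, SE 0.30) were among the higher, and Cxcl12 (-1.80, SE 0.49, -1.05 without GFP+ E7.5 replicate 1) was the lower one. Hoxa3, Hoxb3, Cer1 and Nog lay below 4.38 at E6.5, so the sizes of their changes are uncertain.

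Epiblast genes fell in GFP+ cells between the stages by a median of -0.86 (-0.30 and -1.10 within the replicates). Of 17 members 4 were lower adjusted over the list alone, including Nanog (-2.79, SE 0.41) and Pim2 (-2.23, SE 0.39, camera adjusted p = 8.06e-07, adjusted p = 0.0956 with an estimated correlation). Streak genes had a median of -0.69 (-0.72 and -0.71 within the replicates), with 3 lower and 2 higher of 19 adjusted over the list alone (camera adjusted p = 0.00265, adjusted p = 0.39 with an estimated correlation). Mesp1 (-1.19, SE 0.33) and Fgf8 (-1.70, SE 0.39) were among the lower. Notch pathway genes had a median of 0.38 and extraembryonic ectoderm genes of 0.11, each with 2 higher adjusted over the list alone, of 15 each, and 1 Notch gene lower (camera adjusted p = 0.00643 and 0.00701, adjusted p = 0.39 and 0.424 with an estimated correlation). The Notch call ended without GFP+ E7.5 replicate 2 (0.0559), and the extraembryonic ectoderm call without GFP+ E7.5 replicate 1 (0.142) or with the replicate block (0.0610).

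In GFP+ cells 3 genes passed between the stages, and 3 with the replicate block, of which 1, Msgn1, was shared. The block called Msgn1 (limma adjusted p = 0.0337), Hoxb2 and Lhfp (3.33, SE 0.46, below 4.38 at E6.5 and so of uncertain size), and left Aldh1a2 at 0.0585 and Foxc2 at 0.0571. All 3 calls ended without any 1 of the GFP+ arrays or either GFP- E7.5 array (0 genes), and 3 genes passed without either GFP- E6.5 array. The 3 calls ended also with no filter (limma adjusted p = 0.0517 each) and with only the 4 arrays of the comparison (0.0944 for Aldh1a2, 0.103 for Foxc2, 0.209 for Msgn1), and that of Msgn1 with the random block (0.0626).

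The comparison of E7.5 with E6.5 in GFP- cells asked what differed between the GFP- fractions of the 2 stages. The stages were sorted separately, so no cells were followed from one to the other. Paraxial mesoderm, mesenchymal and Wnt target genes rose there as lists, and epiblast, epithelial and visceral endoderm genes fell as lists. None of these 6 lists passed with an estimated correlation (adjusted p = 0.0956 to 0.369 with an estimated correlation). Aplnr rose by 6.23 (SE 0.30) and Hoxb1 by 6.11 (SE 0.32, limma adjusted p = 0.00116 for both). The other probe set of Aplnr gave a smaller rise of 2.54. Msgn1 rose by 5.18 (SE 0.31) and Cdx1, a posterior homeobox gene and Wnt target, by 5.10 (SE 0.36, limma adjusted p = 0.00202 and 0.00451). Aldh1a2 (5.68, SE 0.55), Foxc2 (5.10, SE 0.46), Meis2 (4.05, SE 0.36), Fn1 (3.06, SE 0.28) and Cited2 (2.77, SE 0.32) also rose. Lefty1, an inhibitor of Nodal, fell by 2.86 (SE 0.32) and the ribosomal protein gene Rpl39l by 2.87 (SE 0.30, limma adjusted p = 0.047 and 0.0331). At E6.5 Aplnr (3.49), Hoxb1 (3.52), Cdx1 (3.39), Aldh1a2 (3.62), Foxc2 (2.96) and Meis2 (4.10) lay below the filter value of 4.38, as did Rpl39l (4.07) at E7.5, so the sizes of these changes are uncertain. Mesp1 was 1.96 higher at E7.5 (SE 0.33, 2.12 and 1.80 within the replicates), which did not pass over all genes (limma adjusted p = 0.121).

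Paraxial mesoderm genes in GFP- cells had a median of 2.21, with 10 of 17 higher adjusted over the list alone, including Aldh1a2, Msgn1 and Cdx1 (camera adjusted p = 7.77e-19, adjusted p = 0.103 with an estimated correlation). Mesenchymal genes had a median of 1.995, with 10 of 17 higher adjusted over the list alone (camera adjusted p = 2.94e-19, adjusted p = 0.103 with an estimated correlation). Wnt targets had a median of 1.15, with 8 higher and 1 lower of 15 adjusted over the list alone (camera adjusted p = 8.61e-09, adjusted p = 0.0956 with an estimated correlation). Streak genes had a median of 1.03 (1.18 and 0.70 within the replicates), with 8 higher and 3 lower, among these Eomes (-2.02, SE 0.53), of 19 adjusted over the list alone (camera adjusted p = 1.08e-05, adjusted p = 0.283 with an estimated correlation). The list of the first heart field had a median of 1.41, with 4 of 13 higher adjusted over the list alone (camera adjusted p = 2.33e-06, adjusted p = 0.279 with an estimated correlation). These members were Hand1 (4.27, SE 0.88), Bmp7 (3.71, SE 0.45), Bmp5 (2.91, SE 0.50) and Tbx20 (2.39, SE 0.54). Of these Bmp7 and Bmp5, and of the paraxial genes Aldh1a2 and Cdx1, lay below 4.38 at E6.5, so their sizes are uncertain. The list of the second heart field had a median of 0.96, with 4 higher and 1 lower of 12 adjusted over the list alone (camera adjusted p = 3.31e-07, adjusted p = 0.135 with an estimated correlation).

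Extraembryonic mesoderm genes in GFP- cells had a median of 0.77, with 5 of 13 higher adjusted over the list alone, including Foxf1 (4.62, SE 1.08) and Phlda2 (3.88, SE 0.48, camera adjusted p = 1.45e-06, adjusted p = 0.241 with an estimated correlation). Hox genes had a median of 0.68 and matrix genes of 0.79, with 3 of 13 and 4 of 18 higher adjusted over the list alone (camera adjusted p = 1.22e-06 and 7.7e-09, adjusted p = 0.271 and 0.14 with an estimated correlation). Guidance genes had a median of 0.76, with 3 higher and 1 lower of 31 adjusted over the list alone (camera adjusted p = 6.96e-06, adjusted p = 0.283 with an estimated correlation). BMP pathway genes had a median of 0.70, with 3 higher and 2 lower of 18 adjusted over the list alone (camera adjusted p = 0.0167, adjusted p = 0.425 with an estimated correlation), and did not pass without GFP- E6.5 replicate 1 (0.0729) or GFP- E7.5 replicate 1 (0.379). Endothelial and haematopoietic genes had a median of 0.48, with 2 higher and 1 lower of 14 adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.491 with an estimated correlation). Kdr (3.30, SE 0.80) and Lmo2 (2.47, SE 0.63, 1.63 without GFP- E6.5 replicate 1, and below 4.38 at E6.5) were higher and Rasip1 (-1.43, SE 0.36) was lower. That call ended with the replicate block (0.0610) and without any 1 of the GFP- arrays (0.0628 and 0.0519 for E6.5 replicates 1 and 2, 0.120 and 0.0515 for E7.5 replicates 1 and 2).

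Epiblast genes in GFP- cells had a median of -1.05, with 3 of 17 lower adjusted over the list alone, Nanog (-2.31, SE 0.41) among them (camera adjusted p = 8.26e-10, adjusted p = 0.0956 with an estimated correlation). Visceral endoderm genes fell with them by a median of -1.31 (-0.92 and -1.62 within the replicates), with 1 of 15, Apoa1 (-2.61, SE 0.53), lower adjusted over the list alone (camera adjusted p = 1.72e-06, adjusted p = 0.369 with an estimated correlation). Epithelial genes had a median of -0.69, with 3 lower and 1 higher of 18 adjusted over the list alone (camera adjusted p = 0.000168, adjusted p = 0.14 with an estimated correlation). The lower ones included Esrp1 (-2.42, SE 0.67), a splicing regulator of epithelia, and Cldn7 (-1.62, SE 0.37). The epithelial call ended without GFP- E7.5 replicate 2 (0.0751). Extraembryonic ectoderm genes passed upward with a median of 0.49 (1.58 and -0.33 within replicates 1 and 2) and 3 of 15 higher adjusted over the list alone, Hand1, Cdx2 (2.21, SE 0.37) and Fgfr2 (2.20, SE 0.28), which mesoderm also expresses (camera adjusted p = 0.00166, adjusted p = 0.369 with an estimated correlation). Without GFP- E7.5 replicate 1 the direction of that list turned (0.735).

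Notch pathway and contractile genes in GFP- cells had medians of 0.58 and 0.19, with 2 of 15 and 0 of 13 higher adjusted over the list alone (camera adjusted p = 0.036 and 0.0414, adjusted p = 0.451 and 0.598 with an estimated correlation). With the replicate block neither passed (0.0509 and 0.0727). The Notch call ended without GFP- E6.5 replicate 2 (0.226) or GFP- E7.5 replicate 2 (0.166). The contractile call ended without GFP- E6.5 replicate 1 (0.255), GFP- E7.5 replicate 2 (0.346), GFP+ E7.5 replicate 1 (0.0530) or GFP+ E7.5 replicate 2 (0.0522).

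In GFP- cells 11 genes passed between the stages (9 up, 2 down), against 39 (29 up, 10 down) with the replicate block, which held all 11. Leaving out 1 array gave 3 genes without GFP- E6.5 replicate 1 or GFP- E7.5 replicate 2, 4 without GFP- E6.5 replicate 2, 6 without either GFP+ E6.5 array, 7 without GFP- E7.5 replicate 1 and 10 without either GFP+ E7.5 array. With only the 4 arrays of the comparison 4 genes passed, Meis2 did not pass with the mean of all probe sets (limma adjusted p = 0.195), and with array weights Lefty1, Cited2 (both 0.0766) and Rpl39l (0.0569) did not. Lefty1 (0.0790) and Cited2 (0.0735) did not pass with the random block, nor Cited2 after centring (0.0632).

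The interaction of fraction and stage asked whether the difference between fractions itself differed at E7.5 from that at E6.5. Streak, mesenchymal, Wnt and first heart field genes had negative median interactions, and epithelial, visceral endoderm and definitive endoderm genes had positive ones. With an estimated correlation 0 of these 7 lists passed (adjusted p = 0.0956 to 0.378 with an estimated correlation). Streak genes had a median interaction of -1.42 (-1.46 and -1.54 within the replicates), with 7 of 19 lower adjusted over the list alone (camera adjusted p = 1.71e-13, adjusted p = 0.135 with an estimated correlation). Mesp1 was at -3.15 (SE 0.46, -3.13 and -3.17 within the replicates), Mixl1 at -2.92 (SE 1.54, -3.65 and -2.18 within the replicates, -1.22 without GFP- E6.5 replicate 1) and Dll3 at -2.60 (SE 0.83). Mesenchymal genes had a median of -0.74, with 4 of 17 lower adjusted over the list alone (camera adjusted p = 5.26e-06, adjusted p = 0.283 with an estimated correlation), and among them Snai1 was at -2.59 (SE 0.48) and Fn1 at -2.55 (SE 0.40). Wnt targets had a median of -0.74, with 3 of 15 lower adjusted over the list alone (camera adjusted p = 1.4e-05, adjusted p = 0.0956 with an estimated correlation). The list of the first heart field had a median of -0.85 and 1 of 13 lower adjusted over the list alone (camera adjusted p = 0.00172, adjusted p = 0.378 with an estimated correlation), and did not pass without GFP- E6.5 replicate 1 (0.0511) or GFP- E7.5 replicate 2 (0.0528).

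Visceral endoderm genes had a median interaction of 1.96 (1.55 and 1.94 within the replicates), with Apoa1 at 2.99 (SE 0.75) and Rbp4 at 2.73 (SE 1.05, 1.74 without GFP- E6.5 replicate 2; camera adjusted p = 1.01e-09, adjusted p = 0.283 with an estimated correlation). Epithelial genes had a median of 0.81, with Krt18 at 2.25 (SE 0.60, camera adjusted p = 1.5e-06, adjusted p = 0.0956 with an estimated correlation), and definitive endoderm genes of 0.90, with Cer1 at 4.17 (SE 1.69; camera adjusted p = 0.000261, adjusted p = 0.283 with an estimated correlation). Cer1 was at 1.18 and 7.17 within the replicates and at 2.03 without GFP- E6.5 replicate 2, and lay below 4.38 in GFP+ cells at E6.5, so its size is uncertain. In these 3 lists 0 of 15, 0 of 18 and 0 of 12 members passed adjusted over the list alone. FGF pathway genes had a median of -0.33, with 1 of 19, Spry1 (2.64, SE 0.41), past it upward adjusted over the list alone (camera adjusted p = 0.0435, adjusted p = 0.279 with an estimated correlation). Matrix genes had a median of -0.29, with 1 of 18 lower adjusted over the list alone (camera adjusted p = 0.0341, adjusted p = 0.425 with an estimated correlation). With the replicate block neither the FGF (0.129) nor the matrix list (0.118) passed. The FGF call ended without 6 of the 8 arrays (GFP+ E6.5 replicate 1 0.0885, GFP+ E7.5 replicate 2 0.564, GFP- E6.5 replicates 1 and 2 0.0563 and 0.131, GFP- E7.5 replicates 1 and 2 0.135 and 0.0751). The matrix call ended without GFP- E6.5 replicate 1 (0.442), GFP- E7.5 replicate 1 (0.217), GFP+ E6.5 replicate 2 (0.0692) or GFP+ E7.5 replicate 1 (0.0577).

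Limma called 0 genes for the interaction, with or without the replicate block, 2 with trend and robust moderation, and 1, Aplnr (-4.09, SE 0.43), with a random block (limma adjusted p = 0.0129, against 0.285 without it), of uncertain size since its GFP- level at E6.5 lay below 4.38. On the other probe set of Aplnr the fractions differed by 2.08 at E6.5 and 1.21 at E7.5, against 5.11 and 1.02 on the one used. At an unadjusted p under 0.05 there were 317 genes, and 761 with the replicate block, where chance gives 585.3.

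**Figure D2:**
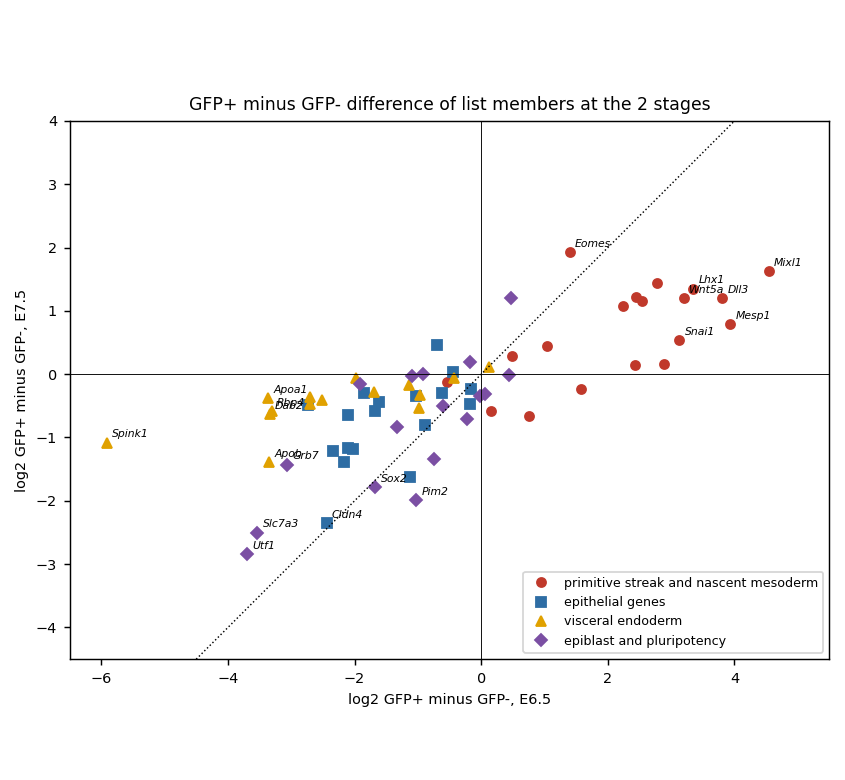
Each point is a gene, with its log2 GFP+ minus GFP- difference at E6.5 on the horizontal and at E7.5 on the vertical axis; circles are streak, squares epithelial, triangles visceral endoderm and diamonds epiblast genes, and the dotted line marks equality. Streak genes lie at a median of 2.44 at E6.5 and 0.79 at E7.5, and epithelial genes at -1.64 and -0.54.

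Across the 11706 genes, the GFP+ minus GFP- differences at E6.5 and E7.5 correlated with r = 0.255 (Spearman rho 0.157; r = 0.146 without GFP+ E7.5 replicate 1), and the stage changes in GFP+ and GFP- cells with r = 0.376 (rho 0.222). Genes are not independent replicates. All 3 genes that rose between the stages in GFP+ cells, Aldh1a2, Foxc2 and Msgn1, were among the 9 that rose in GFP- cells. With the replicate block the 3 shared genes were Hoxb2, Lhfp and Msgn1. Both comparisons use 1 estimate of the spread and arrays that share replicate numbers, so no chance overlap is given. No gene passed in both fraction comparisons. Of the 28 lists, 6 passed in none of the 5 contrasts. The lowest camera adjusted p was 0.142 for anterior epiblast and neural genes, 0.168 for surface ectoderm, 0.0522 for erythroid cells, 0.279 for the cell cycle, 0.14 for dissociation stress and 0.508 for X inactivation and sex-linked genes.

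**Figure D3:**
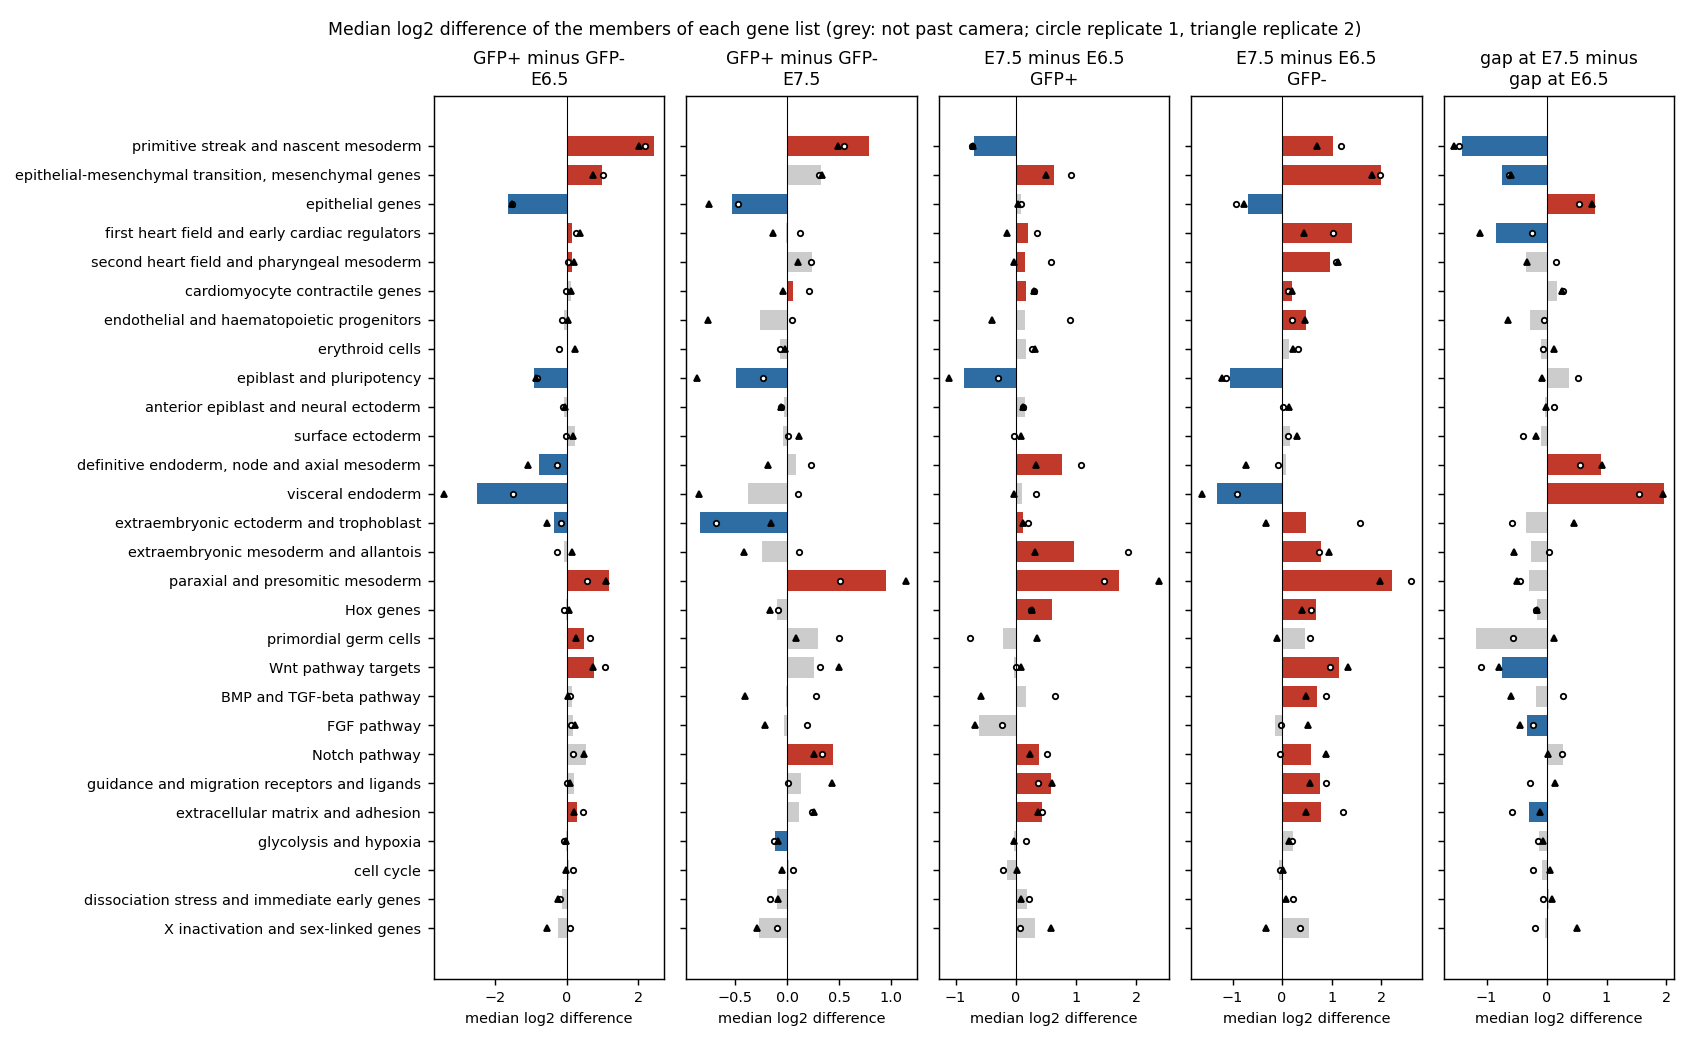
Median log2 change of the members of each of the 28 gene lists (horizontal bars) in the 5 contrasts; red bars passed the camera test upward and blue bars downward, grey bars did not pass, and circles and triangles give the medians within replicates 1 and 2. The longest bars at E6.5 are those of streak genes (2.44) and visceral endoderm genes (-2.52).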

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

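The tests of explanations in this part were chosen after the results were seen, whereas the interaction itself was planned. A test of the difference between the stages singled out 9 gene lists whose GFP+ minus GFP- difference differed between E6.5 and E7.5. The median interactions were -1.42 for streak genes, -0.74 for mesenchymal genes, -0.74 for Wnt targets, -0.85 for the first heart field, -0.33 for the FGF pathway and -0.29 for matrix genes. They were 0.81 for epithelial genes, 0.90 for definitive endoderm genes and 1.96 for visceral endoderm genes. All 9 passed with camera's preset correlation and 0 with an estimated one (lowest adjusted p = 0.0956 with an estimated correlation).

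The smaller gap of streak genes at E7.5 was weighed against 2 technical explanations. Entry of GFP+ cells into the GFP- fraction would leave GFP+ cells as they were, but streak genes were lower at E7.5 in GFP+ cells in both replicates (-0.71 in the one nearer 0, against -0.35 to 0.17 for 10000 random lists of matched expression without the outer 2.5% on each side; 3 of 19 lower and 2 higher adjusted over the list alone, adjusted p = 0.39 with an estimated correlation). Entry of GFP- cells into the GFP+ fraction would leave GFP- cells as they were, but streak genes were higher there in both (0.70 in the one nearer 0, against -0.32 to 0.25; 8 of 19 higher and 3 lower, adjusted p = 0.283 with an estimated correlation). These values argue only weakly against entry in 1 direction as the whole cause. The 2 stage changes are the parts of the flagged interaction itself, and they include development between the stages. Random lists also ignore correlation between genes. Mixing in both directions at E7.5 would lower streak genes in GFP+ and raise them in GFP- cells, as seen, and may be the cause, as may a delay of the reporter or Mesp1 expression that passes on while the stable H2B-GFP persists, and none of these was excluded.

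Epithelial genes were lower in GFP+ cells at E6.5 together with visceral endoderm genes, so visceral endoderm cells in the GFP- fraction were weighed as the cause. The visceral endoderm gap was larger in replicate 2 than in replicate 1 by a median of -1.43, while the epithelial gap differed by 0.046. The epithelial gap thus did not follow the visceral endoderm gap. Its difference lay within the range of matched random lists (-0.35 to 0.27), and each replicate gives 1 gap. This test therefore could not tell the explanation apart from a difference of the epiblast itself. Visceral endoderm is an epithelium too, and the GFP sort alone would not remove it, so a contribution may remain. A biological difference between cells that have and have not left the epithelium stays open and was not tested.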

How the results depend on the processing

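Alternatives with both quantile normalization and the replicate block, with each probe set on its own, and with estimated correlation or fry plus the block were chosen after seeing the data. All 23 calls of named genes kept their direction under every alternative run, which was largely fixed in advance. Apart from Cited2 these genes were named for groups that did not overlap, so leaving out 1 array could not turn them. Blocks and moderation leave the fitted change of a gene as it is. Of named gene values under other settings, 5500 kept their direction and their side of the threshold, 99 came to pass and 40 no longer passed. The direction turned in 13, which passed in neither fit. With 1 array left out these were 3979, 7, 137 and 157. Of list results under other settings, 1241 kept their direction and side of the threshold, 27 came to pass and 241 no longer passed. The direction turned in 31, which passed in neither fit, and so it did in 70 with 1 array left out. Of 62 list calls, 40 passed without each of the arrays in turn.

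Lists: 0 of the 62 calls passed with an estimated correlation, 0 with that and the replicate block, 13 with fry and 26 with fry and the block. Camera with an estimated correlation had few residual degrees of freedom (4, or 3 with the block). Its lowest adjusted p was 0.0956 in each of the 5 contrasts. This failure alone cannot show that a list did not shift, nor that the preset correlation holds. Whether the few degrees of freedom or the correlation between members ended the calls was not tested. The replicate block kept 54 calls, added 1 and changed no call but those given with the results. Leaving out 1 array gave 56 (without GFP- E7.5 replicate 1) to 68 calls. Without that array the extraembryonic ectoderm list turned direction between the stages in GFP- cells (0.735) and in the interaction (0.0422, against 0.396 with all arrays). Replicate 2 then stands alone for its group and is assumed to vary like the others. Over the arrays left out, the adjusted p of this list ran from 1.07e-09 to 0.735 between the stages and from 0.000125 to 0.890 in the interaction.

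Genes at E6.5, 9 with all arrays: 21 with the stricter filter, 20 with trend and robust moderation, 0 with only 4 arrays, 30 with the replicate block, 173 (73 up, 100 down) with the random block, 16 (9 up, 7 down) after quantile normalization, 28 with that and the block, 19 (13 up, 6 down) after centring, 15 with weights and 4 with probe sets. Leaving out 1 array gave 0 to 1. Genes between stages in GFP- cells, 11: 29, 28, 4 and 39 for the first 4 of these, 17 with the mean of probe sets, 26 (19 up, 7 down) after quantile normalization, 55 with that and the block, 30 (26 up, 4 down) after centring and 19 with probe sets. Leaving out 1 array gave 3 to 10. Genes between stages in GFP+ cells, 3: 0 with no filter, 6 with the stricter filter, 0 with 4 arrays, 8 after centring, 5 with weights, 1 with quantile normalization and the block, and 0 with probe sets. Leaving out 1 array gave 0 to 3. At E7.5 the random block gave 1 gene. In the interaction trend and robust moderation gave 2 and the random block 1, and leaving out 1 array gave 0 for both and for genes changed at both stages. An array outside a pairwise comparison enters it only through the shared spread and its degrees of freedom, so counts without such an array moved for that reason. For the other counts that moved, the cause was not tested. Correlations of changes were 0.146 to 0.247 between stages and 0.278 to 0.332 between fractions with 1 array left out. Other scalings moved the median of all genes by under 0.1.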

Other observations

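The tests of explanations and the relation of Hox genes in this part were chosen after the results were seen. In GFP- cells at E7.5, some members of lists that did not pass, picked after their values were seen, stood above the GFP+ cells in both replicates. Hbb-bh1 was at 5.45 and 5.99 on the 2 GFP- arrays, and below 4.38 on the GFP+ arrays. Tfap2a, a gene of surface ectoderm, was at 6.95 and 7.35 on the GFP- arrays, and its GFP+ minus GFP- difference was -2.20 (SE 0.60). Apela, which encodes a ligand of the Aplnr receptor, was at 6.53 and 8.60 (difference -2.26, SE 0.71, -1.23 without GFP- E7.5 replicate 2), the chemokine gene Cxcl12 differed by -2.16 (SE 0.49, -1.42 without GFP+ E7.5 replicate 1) and Bmp5 by -1.67 (SE 0.50). None of these passed over all genes without a block, and the erythroid and surface ectoderm lists did not pass at E7.5 (camera adjusted p = 0.106 and 0.671). Hba-a1 of the erythroid list and Msx2 of the surface ectoderm list were higher in GFP+ cells in both replicates, by 0.52 and 1.12. Nanog fell by 2.79 in GFP+ and by 2.31 in GFP- cells between the stages adjusted over the epiblast list alone, while Pou5f1 was at -0.92 (SE 0.32) and -0.55 (SE 0.32).

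The GFP+ arrays at E7.5 differed from each other in the extraembryonic mesoderm list, with replicate 1 above replicate 2 by a median of 0.76 (Hand1 at 10.33 and 7.92). This list was picked for that difference, and its medians in the other 3 groups were -0.34, -0.46 and -0.54. Of 14 endothelial and haematopoietic genes, 12 were higher in replicate 1, among them Kdr (9.19 and 7.27) and Etv2 (8.46 and 5.88), and Fli1 (4.58 and 4.80) and Pecam1 (3.70 and 4.51) were lower. Elsewhere 5 (GFP- E6.5), 1 (GFP+ E6.5) and 7 (GFP- E7.5) of these 14 were higher in replicate 1. Other lists differed too between the GFP+ E7.5 arrays. In replicate 1, 15 of 18 BMP pathway and 13 of 17 epiblast genes were higher, and 15 of 17 paraxial mesoderm genes were lower. Swapped fraction labels in replicate 2 would reverse epithelial genes, which were lower in its GFP+ array by a median of -0.75 (adjusted p = 0.0956 with an estimated correlation over both replicates). Which territories the 50 cells came from, or the exact stage of the embryos, may differ between the replicates, and neither was tested.

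Over 13 Hox genes, the paralogue number and the log2 stage change correlated negatively in GFP+ cells (Spearman rho -0.77, Pearson r -0.72; permutation p = 0.00325, adjusted p = 0.0065) and in GFP- cells (rho -0.64, r -0.61; permutation p = 0.0218, adjusted p = 0.0218; 100000 permutations, 2 relations). These correlations are across genes, which are not independent replicates. Hoxd9 differed from this order, at 0.99 in GFP+ and 1.55 in GFP- cells, but at -0.20 and -0.05 without replicate 1 of the same fraction at E7.5. Other genes also lay out of order. Hoxa2 rose less than Hoxa3 in GFP+ (0.93 against 2.03) and in GFP- cells (0.48 against 3.27). Hoxa3 lay below 4.38 at E6.5 in GFP+ cells, so that size is uncertain. The order held only in part, and 2 stages cannot show an order of activation.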
